A study of Mus musculus with 12 samples.

How the data were processed

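RNA-seq was analysed from 12 mouse liver cell cultures in 4 groups of 3: hepCLiP and bilCLiP cells, each in 2D and in 3D culture. Per the labels, hepCLiP cells were derived from hepatocytes and bilCLiP cells from biliary epithelial cells. The 2D cultures were kept on collagen in small hepatocyte medium with 10% fetal bovine serum (FBS) and 3 small molecules, the kinase inhibitor Y-27632, the TGF-beta receptor inhibitor A83-01 and the GSK3 inhibitor CHIR99021. For 3D, per the labels, cells formed spheroids in microwells over 3 days in the same medium without FBS. The spheroids were then kept in suspension for 6 to 8 days with oncostatin M, a cytokine of the interleukin 6 family, at 10 ng/ml.

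Groups were taken from the sample titles. The treatment tag of hepCLiP 2D replicate 3 says 3D, and that of the 3 bilCLiP 3D samples says 2D. The log2 CPM of hepCLiP 2D replicate 3 correlated at 0.944 to 0.953 with the other hepCLiP 2D libraries and at 0.814 to 0.852 with the hepCLiP 3D libraries, and results without it are among the alternatives. The genotype tag says RosaConfetti, a multicolour reporter at the Rosa26 locus, for hepCLiP replicates 1 and 3. It says RosaYFP, a yellow fluorescent protein reporter at that locus, for hepCLiP replicate 2 and all bilCLiP samples.

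The authors deposited a table of raw gene counts and a table of normalized counts. The submitters' processing notes name STAR 2.7.10b, featureCounts 2.0.1, DESeq2 without a version and the GRCm39 genome build. The annotation, the counting options and the strand setting are not given in the sources used here, so overlapping and antisense genes could not be separated. In the authors' normalized table (unit signal), each sample's values equal the raw counts divided by a constant within a relative tolerance of 0.001 for every gene. The raw counts were the basis of the main results, and the normalized table entered an alternative. The count table holds 53599 genes, of which 24092 have no count in any sample. Total counts ran from 16142365 to 21253382 per library. Within groups, no pair of libraries was identical, and counts of each pair differed by far more than sampling noise.

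Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filterByExpr filter kept 14798 genes. Libraries were scaled by TMM, and CPM values are counts scaled by the TMM effective library sizes. A robust quasi-likelihood fit (glmQLFit, glmQLFTest) with 4 group means over all 12 samples gave 5 contrasts: 3D against 2D within each origin, bilCLiP against hepCLiP within each culture, and the difference between the culture effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the number of calls of at least 2-fold is given beside. All adjusted p-values of genes come from this test unless another tool is named. Standard errors (SE) were computed from the log2 fold change and the F statistic. Nothing in the labels says whether replicates came from separate animals, so p-values measure only the spread between these samples.

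For a gene with 0 counts in every library of a group, the fold is given as a lower bound against 3 counts summed over that group. With 1 to 3 counts, the ratio is given with its exact 95% interval. Both cover counting error only, because PCR copies are not independent molecules. Members of near-identical families (Serpina1, Serpina3, Saa, Cyp2c, Cyp2d, Cyp2a and Orm) are uncertain, since reads can be split between copies.

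A total of 28 gene lists was fixed, and 24 had the 5 tested members needed for a list test. Lists were tested with limma 3.58.1's camera at a preset correlation between genes of 0.01, adjusted over all lists and contrasts. Camera with an estimated correlation and limma's fry were run beside it, and with the estimated correlation no list passed in any of the 5 contrasts. Fry, which asks whether a list's genes move one way and does not compare them with other genes, called 17 lists with culture in hepCLiP and 16 in bilCLiP, against 16 and 14 by camera. The level of a list in a library is the mean of log2(CPM + 1) over its members. Levels were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

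The named genes followed a fixed rule. This rule, the gene lists, the tests and the alternatives were set before the data were examined, except where a setting is said to have been chosen later. Named were the 6 largest rises and the 6 largest falls per contrast, among called genes with non-overlapping groups and a mean of at least 5 CPM in a group, leaving out unnamed gene models. Added were 15 marker genes, whatever their values, and up to 4 called members per list with the largest changes. Other genes, in the report and in the additional observations, were chosen after their values were seen. Some genes that the rule named are not reported here.

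Same-numbered libraries of the 2 cultures of one origin deviated together from their group means, with correlations of 0.497 to 0.508 for hepCLiP and 0.429 to 0.523 for bilCLiP. They also share a genotype, which sets apart only hepCLiP replicate 2. Mainly on the correlations, the numbers were taken as pairing the cultures but not the origins. The main fit leaves this pairing out, and a fit with the replicate number as a block was an alternative. The other alternatives were DESeq2 1.42.0 size factors and its Wald test, limma on the deposited normalized counts, other filters, fits of only the 2 groups compared, RosaYFP samples only, a test against a 2-fold threshold, other pseudocounts and each library left out. A limma fit with origin and replicate number together as a random block was chosen after seeing the data.

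The pipeline was tested on simulated counts for 14798 genes, with 100 genes changed 2-fold and 100 changed 4-fold in each contrast. The changed genes were drawn from those with a mean of at least 5 CPM over the groups and counts in every group. The rates below therefore do not cover genes with fewer counts. It called 32% of the 2-fold and 86% of the 4-fold changes for hepCLiP 3D against 2D, and 38% and 83% for bilCLiP. Between origins, it called 36% and 78% in 2D and 33% and 86% in 3D. For the difference between culture effects, it called 8% and 69%. False calls made up 3.25% to 8.06% of all calls, the highest between origins in 2D. Chromosomes were looked up by gene symbol in the GENCODE M21 annotation of the GRCm38 build, which matched 97.7% of the tested genes; since that is not the authors' build, no coordinates are given.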

Results

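The transcriptomes of hepCLiP and bilCLiP cells were compared in 2D maintenance culture and after hepatic induction as 3D spheroids, with 3 libraries per group. The title and design of the series ask about plasticity of these cells between the hepatocyte and biliary identities. Each library held 16142365 to 21253382 counts and 12822 to 14067 genes with at least 10 counts. Libraries of one group correlated at 0.944 to 0.969 (Pearson's r of log2 CPM across genes), those of the same culture and other origin at 0.921 to 0.957, and those of the same origin and other culture at 0.751 to 0.860. The first principal component held 62.6% of the variance and the second 9.73%. The 10 most abundant genes took 5.17% ± 0.149 (SD, n = 3) of the counts in hepCLiP 2D and 20.9% ± 2.44 in hepCLiP 3D, against 6.50% ± 0.844 and 19.2% ± 1.46 in bilCLiP. In 3D the leading gene was Trf, the plasma iron carrier transferrin, with 4.52% of hepCLiP and 3.24% of bilCLiP counts.

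In hepCLiP, hepatocyte genes rose from low levels in 2D to high levels in 3D. Alb, encoding albumin, went from 284 ± 357 to 23750 ± 2620 CPM (mean ± SD, n = 3), a log2 fold change of 6.38 ± 1.58 (SE; adjusted p = 0.00998). Apoa1, an apolipoprotein of high-density lipoprotein, rose 239-fold (log2 7.90 ± 1.24), and Cps1, the entry enzyme of the urea cycle, rose from 5.26 ± 7.65 to 1328 ± 962 CPM (adjusted p = 0.00246). The hepatocyte regulators Cebpa and Hnf4a rose by 4.94 ± 0.319 and 1.63 ± 0.289 on the log2 scale, while the fetal liver gene Afp rose by 3.68 ± 1.10. Cyp3a11, a drug-metabolizing cytochrome, had 59.7 ± 100 CPM in 2D and 1379 ± 1690 in 3D and was not called (adjusted p = 0.0920). With the replicate number as a block it was called, at a log2 fold change of 6.80 and an adjusted p of 0.00805, and likewise without hepCLiP 2D replicate 3 (9.54, adjusted p = 0.00971). Cyp2e1 stayed below 5 CPM in every hepCLiP library and was not called.

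In all, 5139 of the 14798 genes tested were called between hepCLiP 3D and 2D, 2497 higher and 2642 lower in 3D, of which 1621 and 1521 changed at least 2-fold. The largest rises under the naming rule were in Serpina3n (log2 13.90 ± 0.723), Wfdc21, A2m, Serpina3k, Tff3 and Serpina3m. Wfdc21 and Tff3, with 2 counts and 1 count summed over the 2D libraries, had ratios of 8870 (95% interval 2455 to 73250) and 3649 (654 to 144200). A2m was at least 726-fold higher, since no read was counted in 2D. Sprr1a, a gene of squamous differentiation, fell from 2844 ± 569 to 3.14 ± 2.94 CPM (log2 -9.82 ± 1.02). Itgb6, Dio3, Clca3b and Sox17 followed, with log2 fold changes of -8.17 to -7.01, and Rarb had 393 counts in 2D and 1 in 3D (ratio 0.00384, 95% interval 9.7e-05 to 0.0215). The Afp call was lost without hepCLiP 2D replicate 1 (adjusted p = 0.0771), 2D replicate 2 (0.0572), 3D replicate 1 (0.0522) or 3D replicate 3 (0.0528), and its log2 fold change was 5.53 without 2D replicate 3. The Tff3 ratio rested on hepCLiP 3D replicate 2, with 169 CPM against 0.366 and 1.74 in the other 3D libraries. Without it the log2 fold change was 5.59 in place of 11.32 and the call was lost (adjusted p = 0.0608), as it was without 2D replicate 3 (0.0541).

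Most members of each hepatocyte list rose in hepCLiP 3D. All 30 secreted plasma proteins rose (median log2 fold change 6.84), among them Plg, Itih3 and Serpina3k. The list's level went from 4.94 ± 0.874 to 11.98 ± 0.217 (exact p = 0.1, the smallest possible). Its camera adjusted p was 4.89e-18, and the adjusted p was 0.184 with an estimated correlation. Of 34 cytochrome P450 and drug metabolism genes 29 rose and none fell (median 5.75, or 5.69 with members at their bounds), such as Cyp2a5, Cyp2d10, Cyp2b10 and Aox3. Of 30 urea cycle and amino acid catabolism genes 26 rose, with Hpd, Arg1, Otc and Haao in front, and of 14 genes of gluconeogenesis and glucose handling 10 rose, such as Gys2, Fbp1 and Pcx. Bile acid synthesis and transport genes rose in 16 of 18 cases, among them the bile acid ligase Slc27a5 (11.11 ± 0.780) and the canalicular bile salt pump Abcb11 (7.23 ± 1.18). Adjusted over the list alone, 30, 31, 28, 10 and 16 members of these 5 lists were called. Camera called all of them, at adjusted p-values of 3.58e-06 or lower, and the adjusted p was 0.162 with an estimated correlation for the P450, urea cycle and gluconeogenesis lists and 0.166 for the bile acid list. Of 15 hepatocyte transcription factors 9 rose, including Creb3l3, Nr5a2 and Ppara, and Foxa2 fell by 0.82 on the log2 scale (camera adjusted p = 0.000262; adjusted p = 0.286 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell.

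Many genes of lipid metabolism also rose in hepCLiP 3D. Of 25 cholesterol synthesis genes 13 rose, or 20 adjusted over the list alone, with Tm7sf2 (from 15.7 ± 5.09 to 102 ± 41.2 CPM), Insig1, Nsdhl and Dhcr7 in front (median 1.30, camera adjusted p = 8.25e-07; adjusted p = 0.518 with an estimated correlation). Fatty acid synthesis genes rose in 9 and fell in 1 of 18 cases, or 10 and 1 adjusted over the list alone, and Scd1, a fatty acid desaturase, rose from 137 ± 66.3 to 2267 ± 336 CPM (list adjusted p = 0.000433; adjusted p = 0.483 with an estimated correlation). Fatty acid oxidation and PPAR alpha targets rose in 16 and fell in 1 of 23 cases, or 17 and 2 adjusted over the list alone, with Fabp1, encoding a fatty acid binding protein, as an example (7.24 ± 0.613). Their camera adjusted p was 4.58e-07, and the adjusted p was 0.162 with an estimated correlation.

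Biliary markers were not called as a list in hepCLiP (median -0.44, camera adjusted p = 0.253). Krt19, a keratin of bile duct cells, fell from 860 ± 336 to 8.74 ± 9.03 CPM (log2 -6.62 ± 1.10, adjusted p = 0.00129). Krt7 fell from 507 ± 319 to 55.8 ± 44.5 CPM and Tspan8 from 516 ± 180 to 47.6 ± 35.7. The Krt7 call was lost without hepCLiP 2D replicate 3 (adjusted p = 0.0703). Spp1, encoding osteopontin, rose 5.08-fold to 13680 ± 2290 CPM. Sox9 had 82.3 ± 40.7 CPM in 2D and 82.2 ± 26.7 in 3D and was not called, nor was Epcam. Of the 27 members 9 fell and 5 rose, or 10 and 5 adjusted over the list alone. The 5 that rose were Aqp1, Muc1, Pkd2, Spp1 and Sstr2, of which Aqp1 was no longer called without 2D replicate 2 (adjusted p = 0.0523) or 2D replicate 3 (0.0517).

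Proliferation and signalling genes changed as well in hepCLiP. Of 40 cell cycle genes 38 fell and none rose (median -2.48, camera adjusted p = 3.22e-16; adjusted p = 0.387 with an estimated correlation), or 39 adjusted over the list alone. Kif23, a mitotic kinesin, fell from 79.5 ± 8.48 to 6.01 ± 2.08 CPM. YAP and TEAD targets fell in 16 and rose in 2 of 24 cases, or 17 and 2 adjusted over the list alone, and Ccn1 fell by 4.52 ± 0.483 on the log2 scale (list adjusted p = 8.3e-07; adjusted p = 0.162 with an estimated correlation). Notch ligands, receptors and targets fell in 6 of 11 cases, among them Hes1, Jag1 and Lfng, whereas the ligand Dll1 rose by 4.17 ± 0.519 (list adjusted p = 0.0182; adjusted p = 0.357 with an estimated correlation; the same 6 and 1 adjusted over the list alone). Mesenchymal and EMT genes fell in 10 of 20 cases and rose in 1, or 11 and 1 adjusted over the list alone, with Vim from 1063 ± 355 to 142 ± 83.3 CPM (list adjusted p = 0.00087; adjusted p = 0.286 with an estimated correlation). Among markers of other cell types, the mesothelial gene Msln fell from 559 to 17.0 CPM (-5.03 ± 0.713), and the fibroblast gene Dcn reached 282 CPM in hepCLiP 3D replicate 1. Acute phase and STAT3 targets, which share Itih4, Fga, Fgb, Fgg and Hp with the secreted proteins, rose in 24 of 30 cases, or 26 adjusted over the list alone, with Saa2 and Orm2 among the largest (list adjusted p = 3.8e-13; adjusted p = 0.162 with an estimated correlation). Of 23 unfolded protein and stress response genes 15 rose and 2 fell, the same counts adjusted over the list alone (list adjusted p = 2.95e-05; adjusted p = 0.357 with an estimated correlation). Xbp1 rose by 2.25 ± 0.195 and Dnajb9 by 2.54 ± 0.273, while Atf3 and Phgdh fell.

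**Figure D1:**
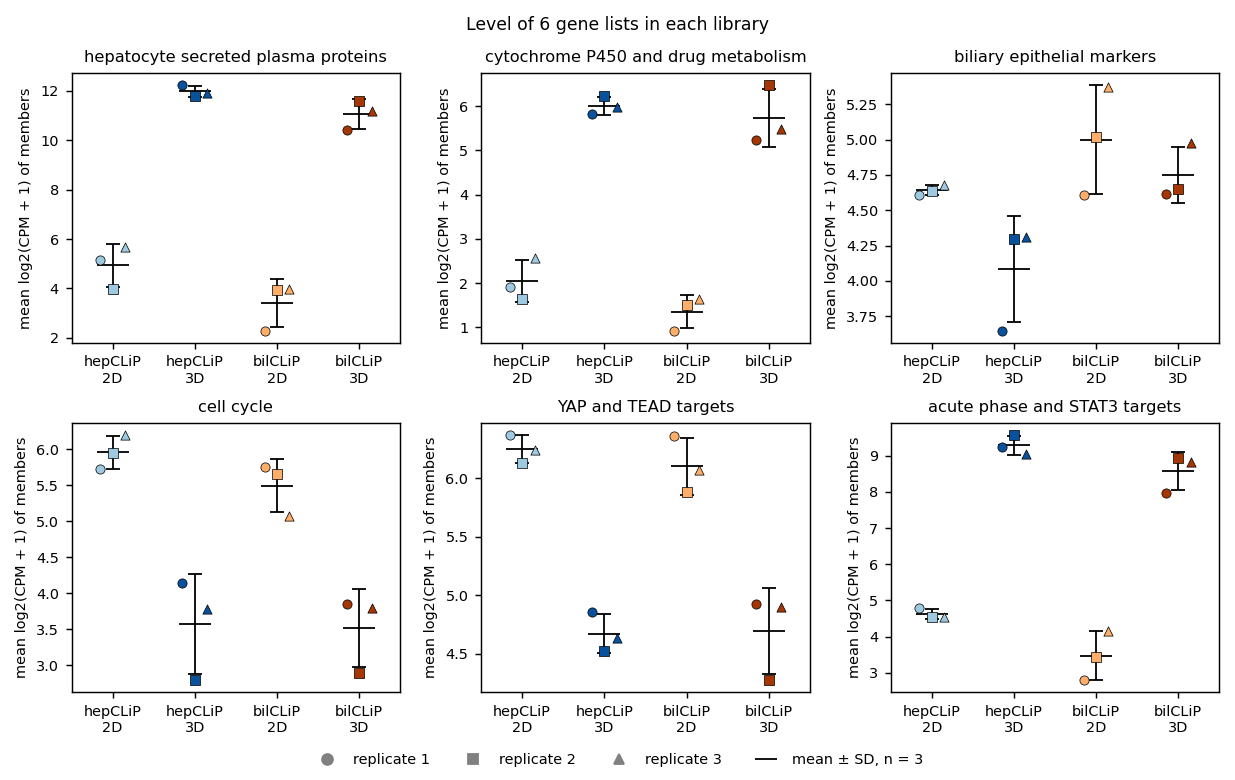
Level of 6 gene lists in each of the 12 libraries, as the mean of log2(CPM + 1) over the list's members (vertical axes, each with its own range, not starting at 0); symbols are replicates 1 to 3, lines and bars the group mean ± SD (n = 3). The secreted protein level was 4.94 in hepCLiP 2D and 11.98 in hepCLiP 3D, against 3.41 and 11.06 in bilCLiP, and the cell cycle level fell in 3D in cells of both origins.

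Geometry, oncostatin M, serum and culture time differ together between 2D and 3D, so the effects of single components cannot be separated. With RosaYFP samples only, 769 genes were called in hepCLiP. This leaves 1 hepCLiP library per culture, which is assumed to vary like the bilCLiP groups, the only source of the spread. In all samples, 1492 genes passed a test against a 2-fold threshold.

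In bilCLiP, hepatocyte markers also rose in 3D. Alb went from 40.0 ± 35.3 to 16290 ± 9010 CPM (log2 8.67 ± 1.74, adjusted p = 0.00413), and Apoa1 rose 818-fold. Cps1 had 2 counts summed over the 2D libraries and 32667 in 3D, a ratio of 23230 (95% interval 6432 to 191900). Cyp3a11 rose from 0.809 ± 1.24 to 1817 ± 448 CPM (11.15 ± 2.61, adjusted p = 0.00884). Cebpa rose by 5.78 ± 0.339 and Hnf4a by 1.47 ± 0.288, and Ttr, encoding transthyretin, rose from 400 ± 325 to 7199 ± 456 CPM. Cyp2e1, with no count in 2D and 0.741 ± 0.285 CPM in 3D, was at least 17.5-fold higher, close to the threshold (adjusted p = 0.0473), and the call was lost when any of 10 libraries was left out (adjusted p 0.0545 to 0.106).

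In total 4485 genes were called in bilCLiP, 2335 higher and 2150 lower in 3D, of which 1548 and 1268 changed at least 2-fold, and 1290 passed the test against a 2-fold threshold. The largest rises were in Serpina3k (at least 38490-fold), Serpina1d, Hpd, Saa2, Serpina3n and Aadac. The largest falls were in Prr9 (at least 113-fold, from 6.87 ± 4.95 CPM), Sprr1a, Clca3b, Dio3, Sox17 and Gzme. Of these, Saa2 (ratio 56140), Clca3b (0.00123) and Gzme (0.00345) had 1 to 3 counts in their lower group, with 95% intervals of 10080 to 2217000, 0.000253 to 0.00359 and 8.7e-05 to 0.0193. Without bilCLiP 3D replicate 1, the log2 fold change of Sox17 was -12.60 in place of -8.07. The Afp rise (3.52 ± 1.08) was lost without bilCLiP 2D replicate 1 (adjusted p = 0.0897), 2D replicate 2 (0.0540), 2D replicate 3 (0.0823), 3D replicate 2 (0.0546) or 3D replicate 3 (0.105).

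Most members of each hepatocyte list rose in bilCLiP 3D. Of the secreted proteins 29 of 30 rose (median 9.17, or 8.58 with members at their bounds), with Plg, Vtn and Serpina1a among the largest. The list's level went from 3.41 ± 0.962 to 11.06 ± 0.602 (exact p = 0.1, the smallest possible). Of the P450 list 31 of 34 rose (median 7.79, or 5.84 with members at their bounds), including Ces1c, Cyp2d9 and Cyp3a25. Urea cycle and amino acid genes rose in 27 of 30 cases, such as Otc, gluconeogenesis genes in 11 of 14, such as G6pc (9.85 ± 1.64), and bile acid genes in 17 of 18, such as Slco1b2 and Abcb11. Adjusted over the list alone, 29, 33, 27, 12 and 17 members of these 5 lists rose. Camera called each at an adjusted p of 8.3e-07 or lower, and for each the adjusted p was 0.162 with an estimated correlation. Transcription factors rose in 10 and fell in 1 of 15 cases, also adjusted over the list alone, and Nr1i2, the pregnane X receptor, rose by 4.79 ± 1.20 (list adjusted p = 0.000262; adjusted p = 0.286 with an estimated correlation). Without bilCLiP 2D replicate 3, the Nr1i2 log2 fold change was 7.21.

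**Figure D2:**
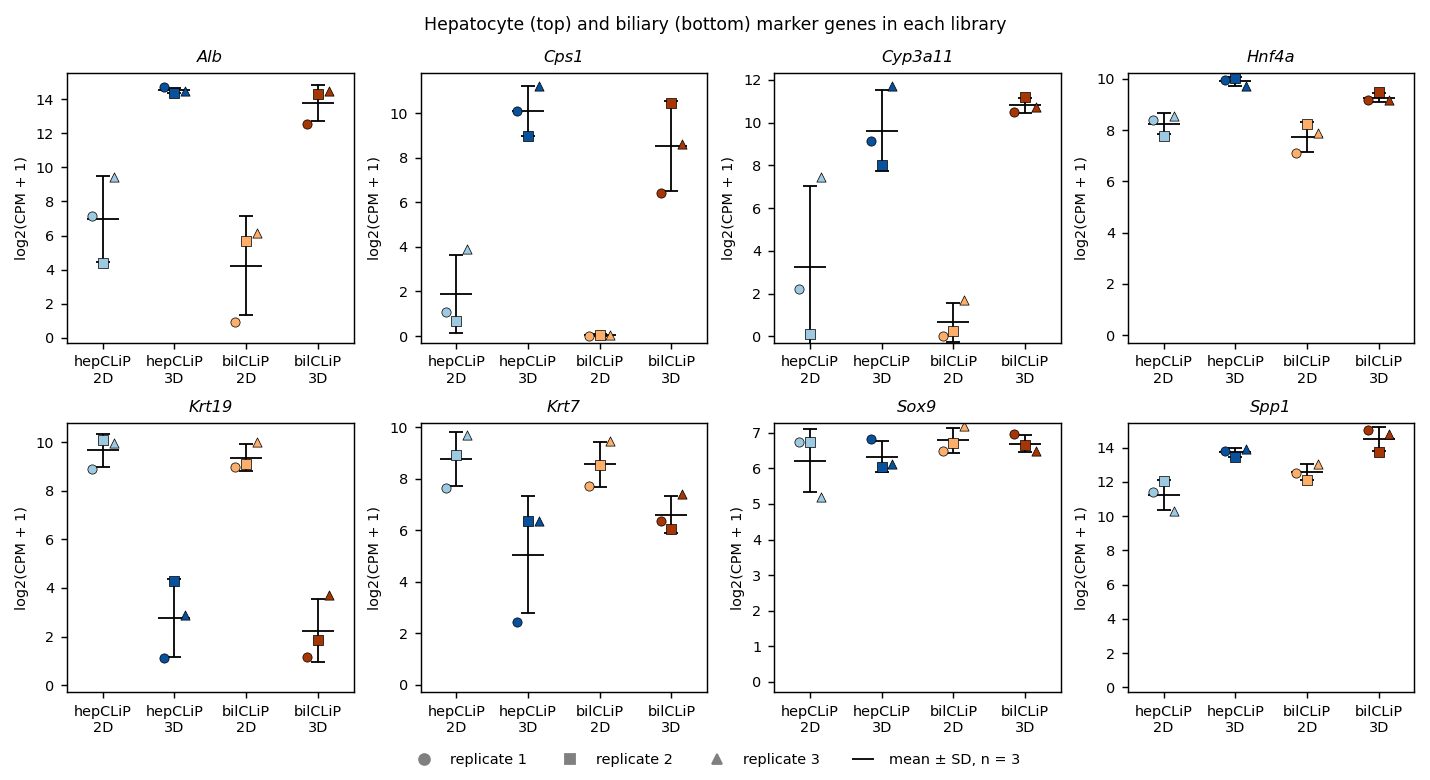
Marker genes in each of the 12 libraries, as log2(CPM + 1) (vertical axes); symbols are replicates 1 to 3, lines and bars the group mean ± SD of the log2 values (n = 3). Krt19 was lower in every 3D library than in any 2D library of the same origin, Spp1 was higher, and Sox9 overlapped between the cultures.

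Of the lipid lists in bilCLiP, cholesterol synthesis rose in 2 of 25 cases, Ebp (1.71 ± 0.253) and Stard4 (0.87 ± 0.223), with the same count adjusted over the list alone. The list was not called (median 0.46, camera adjusted p = 0.0754). Fatty acid synthesis rose in 7 and fell in 2 of 18 cases, also adjusted over the list alone, and was not called (adjusted p = 0.108), though Dgat2 rose by 3.40 ± 0.551. With the replicate number as a block both lists were called, at medians of 0.54 and 0.55 and adjusted p-values of 0.00654 and 0.0482, but the adjusted p was 0.729 and 0.346 with an estimated correlation. The cholesterol list was also called without bilCLiP 2D replicate 2 (adjusted p = 0.00846), 2D replicate 3 (0.0329) or 3D replicate 1 (0.0136), and the fatty acid list without 2D replicate 2 (0.0368), where the adjusted p was 0.665 or higher with an estimated correlation. Fatty acid oxidation genes rose in 15 and fell in 1 of 23 cases, or 18 and 2 adjusted over the list alone, with Fabp1 at 11.10 ± 0.788 (list adjusted p = 3.24e-07; adjusted p = 0.162 with an estimated correlation).

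Among biliary markers in bilCLiP, Krt19 fell from 694 ± 295 to 5.32 ± 5.88 CPM (-7.02 ± 1.12, adjusted p = 0.00126). Krt7 had 427 ± 250 CPM in 2D and 106 ± 56.6 in 3D and was not called (adjusted p = 0.114), but was called with the replicate number as a block (log2 -1.97, adjusted p = 0.0207) or without hepCLiP 3D replicate 1 (0.0316). Spp1 rose 3.98-fold to 24800 ± 10200 CPM, and Slc10a2, the apical bile acid transporter, rose 10.2-fold. Sox9 and Epcam were not called. Of the 27 members 6 rose and 8 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.373).

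Cell cycle genes fell in 38 of 40 cases in bilCLiP and none rose, or 39 adjusted over the list alone, with Bub1 and Kif23 in front (median -2.18, adjusted p = 1.49e-15; adjusted p = 0.389 with an estimated correlation). YAP and TEAD targets fell in 16 and rose in 1 of 24 cases, or 18 and 1 adjusted over the list alone. Ccn1 fell from 727 ± 17.8 to 64.1 ± 25.3 CPM, and Axl fell 6.61-fold. Mesenchymal genes fell in 11 of 20 cases and none rose, or 13 and 1 adjusted over the list alone. Camera called both lists (adjusted p = 4.92e-08 and 4.74e-05), and for each the adjusted p was 0.162 with an estimated correlation. The mesothelial gene Msln fell from 701 to 17.4 CPM. Notch genes fell in 4 and rose in 1 of 11 cases, or 7 and 1 adjusted over the list alone, with Hes1 lower and Dll1 higher (adjusted p = 0.0289, or 0.0576 without bilCLiP 2D replicate 3 and 0.0776 without a low-count filter; adjusted p = 0.387 with an estimated correlation). Acute phase and STAT3 targets rose in 23 of 30 cases, or 25 adjusted over the list alone (adjusted p = 1.77e-15; adjusted p = 0.162 with an estimated correlation). Unfolded protein and stress response genes rose in 13 and fell in 3 of 23 cases, or 13 and 4 adjusted over the list alone (adjusted p = 0.00199; adjusted p = 0.491 with an estimated correlation).

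Fetal liver and progenitor genes went both ways in each origin. In hepCLiP 4 of 18 rose (Afp, H19, Igf2 and Ly6d) and 8 fell, among them Lgr5 (-4.47 ± 0.902), with the same counts adjusted over the list alone. In bilCLiP the same 4 rose and 6 fell, also adjusted over the list alone. H19, an imprinted RNA of fetal liver, had 2182 ± 2280 CPM in hepCLiP 3D and 2671 ± 3540 in bilCLiP 3D, against 1.21 ± 0.210 and 0.408 ± 0.242 in 2D. The list was not called in hepCLiP (adjusted p = 0.165) or bilCLiP (0.292), with medians of -1.26 and -0.55 but means of 0.38 and 0.94. Of 14 Wnt and beta-catenin targets, Lgr5, Axin2, Sp5 and Bmp4 fell in hepCLiP and Cyp1a2 rose. In bilCLiP Bmp4 fell, and Cyp1a2 and Cyp2e1, cytochromes of the perivenous liver lobule, rose. Adjusted over the list alone, 7 fell and 1 rose in hepCLiP and 1 fell and 1 rose in bilCLiP, and the list was not called in either (adjusted p = 0.178 and 0.926; the bilCLiP median was -0.25 and the mean 0.60). The Axin2 call was lost without hepCLiP 2D replicate 2 (adjusted p = 0.0808), 3D replicate 1 (0.0793) or 3D replicate 3 (0.0755). That of Sp5 was lost without 2D replicate 1 (0.0538), 2D replicate 3 (0.0646), 3D replicate 1 (0.0924) or 3D replicate 3 (0.0866), and that of Cyp1a2 in hepCLiP without 2D replicate 1 (0.0806), 2D replicate 2 (0.0706) or 3D replicate 2 (0.0780). Without 2D replicate 3, the Cyp1a2 log2 fold change was 5.04 in place of 3.22.

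The culture effects of the 2 origins were close to each other across genes. Serpina3n rose by 13.90 in hepCLiP and by 15.10 in bilCLiP, and Sprr1a fell by 9.82 and 9.73 on the log2 scale. Pearson's r between the log2 fold changes was 0.907 and Spearman's rho 0.856 over 14798 genes, which are not independent replicates. Of the genes called, 1894 rose in both origins, against 394 for independent lists of these sizes, and 1777 fell in both, against 384. No gene was called in opposite directions. Among genes called in at least 1 origin, 5879 of 5953 had the same sign in both. The effects share no library. Without a filter on low counts, r was 0.597 over 29507 genes.

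**Figure D3:**
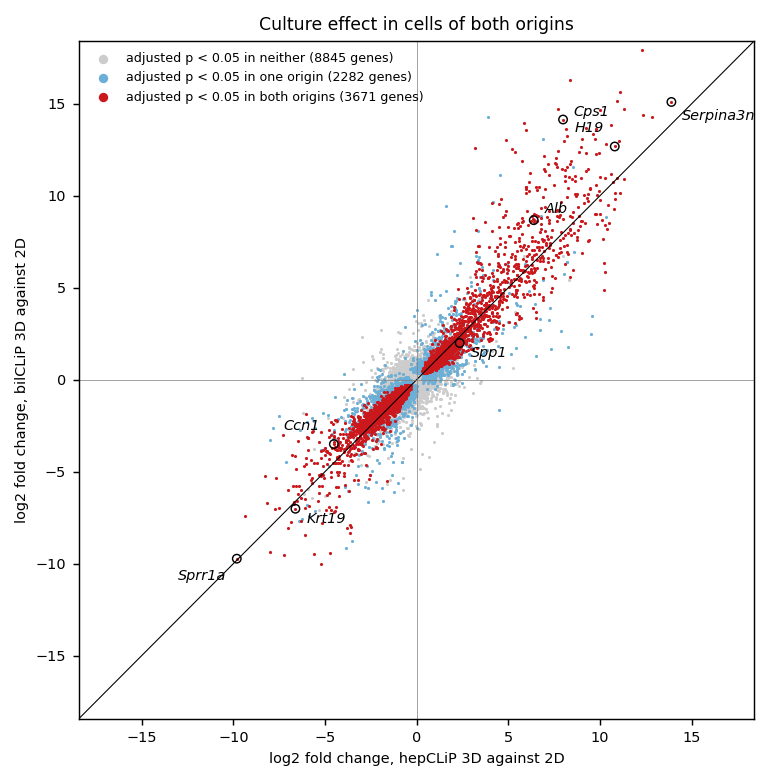
Log2 fold change of 3D against 2D in hepCLiP (horizontal axis) and bilCLiP (vertical axis) for the 14798 genes tested, with the line of equal values. Called in both origins were 3671 genes, in a single origin 2282 and in neither 8845, and the points followed the line with r = 0.907.

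No gene was called for a difference between the culture effects, which asks whether the response to 3D induction depended on origin. Alb rose by 6.38 in hepCLiP and by 8.67 in bilCLiP, a difference of 2.29 ± 1.79 (adjusted p = 1) that was 0.48 without hepCLiP 2D replicate 3. Krt19 differed by -0.40 ± 1.25 and Hnf4a by -0.16 ± 0.399 (adjusted p = 1 for both). The edgeR test gave 532 genes at an unadjusted p under 0.05, 3.60% of those tested, and no adjusted p below 0.937. DESeq2's Wald test called 16 genes and limma on the normalized counts 0. Without hepCLiP 2D replicate 2, 3 genes were called. The median SE of a difference was 0.394 on the log2 scale, and 8% of simulated 2-fold differences were called, so differences of that size were mostly not detectable in this fit. The simulation drew the libraries without pairs, so it does not show what a fit with the replicate number as a block can detect. The fit with that block called 0 genes too.

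Camera called 9 lists for the difference, none with an estimated correlation and none with fry. Cholesterol synthesis genes rose in hepCLiP at a median of 1.30, while the median in bilCLiP was 0.46, a median difference of -1.03 (adjusted p = 3.23e-13; adjusted p = 0.357 with an estimated correlation). None of its 25 members was called, also adjusted over the list alone. Fatty acid synthesis differed by -0.69 (adjusted p = 2.14e-07; adjusted p = 0.294 with an estimated correlation), the P450 list by 1.36, or 1.25 with members at their bounds (1.75e-05; 0.387 with an estimated correlation) and the secreted proteins by 0.84 (6.62e-05; 0.529 with an estimated correlation), of which 4 members were called adjusted over the list alone. The secreted protein call was lost without bilCLiP 2D replicate 1 (median 0.55, adjusted p = 0.147). In RosaYFP samples only, the secreted protein and P450 differences had medians of -0.014 and -0.023 and were not called (adjusted p = 0.684 and 0.128). Other splits of the same libraries gave as many called lists.

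In 2D, 20 genes were called between bilCLiP and hepCLiP, 12 higher and 8 lower in bilCLiP, which asks what distinguishes the origins under equal culture. In both cultures, genotype and sex chromosome transcripts differ along with origin. All bilCLiP libraries are RosaYFP and express Xist, while hepCLiP replicates 1 and 3 are RosaConfetti and express Y chromosome genes. Differences between these groups therefore cannot be assigned to origin alone. Xist, the RNA that coats the inactive X chromosome, had 988 ± 176 CPM in bilCLiP and 0.0609 ± 0.0694 in hepCLiP (13.80 ± 0.639, adjusted p = 4.92e-06). Tm4sf1, a membrane protein gene, had 276 ± 161 against 0.158 ± 0.0575 CPM, and Cyba, encoding a subunit of NADPH oxidase, 18.3 ± 7.90 against 0.0783 ± 0.0957. Sparc, encoding a matrix protein, was 16.8-fold higher in bilCLiP (4.07 ± 0.378), and Dcdc2a and Rassf9 were 7.19-fold and 12.5-fold higher. Kyat3, an aminotransferase gene, was 25.0-fold lower in bilCLiP (-4.64 ± 0.658), followed by Gata4, Hapln4, Prkaa2, Tmem109 and Lrp5.

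None of the 15 marker genes was called between origins in 2D by edgeR, whereas DESeq2's Wald test called Cps1, Cebpa, Cyp2e1, Apoa1 and Cyp3a11, all lower in bilCLiP, and limma on the normalized counts called Cebpa. Cebpa had 1.88 ± 0.409 CPM in bilCLiP and 6.63 ± 0.478 in hepCLiP (-1.82 ± 0.303, adjusted p = 0.0592), and was called without bilCLiP 3D replicate 1 (0.0301) or 3D replicate 2 (0.0152). Alb had 40.0 ± 35.3 against 284 ± 357 CPM and a log2 fold change of -2.83 ± 1.34, which was -1.02 without hepCLiP 2D replicate 3. Krt19 (-0.31 ± 0.858), Krt7 (-0.25 ± 0.858) and Sox9 (0.44 ± 0.381) had adjusted p-values of 0.627 or higher. In the list test, 9 lists were lower and 2 higher in bilCLiP 2D, while fry, which does not compare a list with other genes, called 2, the P450 list (adjusted p = 0.0456) and acute phase and STAT3 targets (0.0289), both lower. The secreted proteins had a median of -1.72 (adjusted p = 1.54e-09; adjusted p = 0.357 with an estimated correlation) and the P450 list -2.03, or -1.85 with members at their bounds (7.45e-08; adjusted p = 0.299 with an estimated correlation). None of their members was called, against 10 and 0 adjusted over the list alone. Biliary markers had a median of 0.44 (adjusted p = 0.0168; adjusted p = 0.428 with an estimated correlation) with no member called on either adjustment. They lost their call without hepCLiP 2D replicate 3 (0.0663) or bilCLiP 2D replicate 3 (0.201), at medians of 0.166 to 0.314. Also lower were hepatocyte transcription factors, fatty acid oxidation, acute phase, cell cycle, urea cycle, gluconeogenesis and bile acid lists, at medians of -1.51 to -0.11 (adjusted p = 0.0464 or lower; adjusted p = 0.286 or higher with an estimated correlation). None of their members was called, while adjusted over the list alone 5 acute phase, 3 urea cycle, 3 fatty acid oxidation and 1 gluconeogenesis genes were lower and the transcription factors had 1 higher and 2 lower. The calls of fatty acid oxidation were lost without any of 6 libraries, and those of transcription factors, bile acids and cell cycle without any of 2, 2 and 1. In these fits the medians ran up to -0.039, -0.38, -0.45 and -0.29. Fits of only the 2 groups also ended the calls of transcription factors (0.0756), bile acids (median -0.42, adjusted p = 0.273) and fatty acid oxidation (0.118). A filter at a CPM of 1 ended that of fatty acid oxidation (0.0526). In RosaYFP samples only, the calls of biliary markers (adjusted p = 0.139), transcription factors (0.370), gluconeogenesis (0.131), bile acids (0.40) and fatty acid oxidation (0.0509) were lost. The 13 mitochondrially encoded genes had a median of 0.67 (adjusted p = 0.000251; adjusted p = 0.518 with an estimated correlation), and mitochondrial transcripts made up 3.67% ± 0.759 of bilCLiP 2D and 2.28% ± 0.158 of hepCLiP 2D counts.

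At an unadjusted p under 0.05, 2146 genes (14.5%) differed between origins in 2D, and DESeq2's Wald test called 559 while limma on the normalized counts called 38. Of the Wald calls 32.7% were higher in bilCLiP, against 60% in the edgeR test. Fitted alone, the 2 groups gave 5 calls, as did the test against a 2-fold threshold. RosaYFP samples only leave 1 hepCLiP library per culture, so effect sizes were compared. For the genes called between origins in 2D or 3D, these had a median ratio of 1.02 to those in all samples (0.700 to 1.48). The genes were chosen by their call in all samples, which favours genes whose hepCLiP lines agree, so this ratio decides nothing about genotype. Leaving out single libraries gave 6 to 31 calls. The lowest count, 6, was without bilCLiP 2D replicate 3, and 31 was without hepCLiP 2D replicate 2. Other counts more than 1.5 times from 20 were 8 without bilCLiP 2D replicate 1, 10 without bilCLiP 3D replicate 2, 11 without hepCLiP 2D replicate 1 or bilCLiP 2D replicate 2, and 13 without hepCLiP 2D replicate 3. The Gata4 call was lost when any of 11 libraries was left out, those of Rassf9 and Prkaa2 for any of 9, Dcdc2a 8, Kyat3 and Hapln4 5 and Cyba and Lrp5 2, while Xist, Tm4sf1 and Sparc remained called without any single library.

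In 3D, 15 genes were called between origins, 8 higher and 7 lower in bilCLiP, all at least 2-fold. Xist (12.94 ± 0.622), Tm4sf1 (8.07 ± 0.647), Sparc (6.24 ± 0.448) and Dcdc2a (3.87 ± 0.457) were higher in bilCLiP, and Cyba was at least 181-fold higher, since no read was counted in hepCLiP 3D. Cryab, a small heat shock protein gene, had 51.6 ± 16.1 against 8.91 ± 3.69 CPM. Kyat3 was lower by -5.79 ± 0.697 (log2), with 3.33 ± 2.03 against 184 ± 63.5 CPM, and Tmc5, Nat8f2, Nudt18, Hapln4 and H1f2 were lower too.

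None of the 15 marker genes was called between origins in 3D by edgeR, and DESeq2's Wald test called Cebpa, lower in bilCLiP. Alb had 16290 ± 9010 CPM in bilCLiP and 23750 ± 2620 in hepCLiP (-0.54 ± 1.25), Hnf4a 620 ± 78.2 against 959 ± 111 (-0.63 ± 0.283) and Cyp3a11 1817 ± 448 against 1379 ± 1690. In the list test, 7 lists were lower and 2 higher in bilCLiP 3D, while fry called 1, fatty acid synthesis (adjusted p = 0.0269), as lower. Cholesterol synthesis had a median of -0.74 (adjusted p = 1.5e-07; adjusted p = 0.491 with an estimated correlation) and fatty acid synthesis -0.72 (6.8e-08; adjusted p = 0.286 with an estimated correlation). Their called members numbered 0 and 1, the latter Thrsp, and 3 and 4 adjusted over the list alone. Biliary markers had a median of 0.86 (adjusted p = 0.000676; adjusted p = 0.286 with an estimated correlation), again with no member called on either adjustment. Also lower were the secreted protein, urea cycle, gluconeogenesis, acute phase and hypoxia lists, at medians of -0.65 to -0.41 (adjusted p = 0.0262 or lower; adjusted p = 0.428 or higher with an estimated correlation). No member was called, against 1 of gluconeogenesis and 5 of hypoxia adjusted over the list alone. The count of called lists was 5 without bilCLiP 3D replicate 1, which ended all of these calls but hypoxia, and 18 without bilCLiP 3D replicate 2. Without bilCLiP 3D replicate 1 the medians were -0.307 for secreted proteins and -0.169 for the urea cycle. Over the libraries whose absence ended their calls, the medians were -0.461 to -0.268 for gluconeogenesis and -0.36 to -0.295 for acute phase targets. Without hepCLiP 3D replicate 2 the calls of gluconeogenesis (0.0501) and acute phase (0.0562) were lost, as was gluconeogenesis without hepCLiP 3D replicate 3 (0.162). In RosaYFP samples only, the secreted protein (0.117) and gluconeogenesis (0.0515) calls were lost. The mitochondrially encoded genes had a median of 0.77 (adjusted p = 5e-05; adjusted p = 0.491 with an estimated correlation). Mitochondrial transcripts made up 3.69% ± 1.04 of bilCLiP 3D and 2.10% ± 1.65 of hepCLiP 3D counts, with 3.99% in hepCLiP 3D replicate 3 alone. Without that library, the list's difference of culture effects was 0.998 in place of 0.0753. Camera then called it (adjusted p = 2.54e-05), though no list passed with an estimated correlation.

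Unadjusted, 2461 genes (16.6%) had a p under 0.05 between origins in 3D, and DESeq2's Wald test called 652, of which 40% were higher in bilCLiP against 53.3% in the edgeR test, while limma on the normalized counts called 26. Fitted alone, the 2 groups gave 3 calls and the test against a 2-fold threshold 7. Without hepCLiP 3D replicate 3, 251 genes were called. The count was 3 without hepCLiP 3D replicate 1, 4 without bilCLiP 3D replicate 1 or 3, 6 without bilCLiP 3D replicate 2, 8 without bilCLiP 2D replicate 1 and 9 without bilCLiP 2D replicate 3. The calls of Cryab, Tmc5 and H1f2 were each lost when any of 9 libraries was left out, and those of Hapln4, Nudt18, Nat8f2, Kyat3, Cyba and Dcdc2a when any of 7, 5, 4, 4, 3 and 2 was.

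Xist, Tm4sf1, Cyba, Sparc, Dcdc2a, Kyat3 and Hapln4 were called in both cultures, with the same sign. Pearson's r between the log2 fold changes in 2D and in 3D was 0.576 across 14798 genes. The comparisons share no library, but the replicate numbers pair the cultures, so they are not independent. On differences of mean log2 CPM r was 0.638, while 9 other splits of the 6 lines, with the origin effects removed, gave 0.431 to 0.559, in a test chosen after seeing the data. These splits are too few for a share under 0.05, and genotype and sex chromosome transcripts differ along with the real split.

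**Figure D4:**
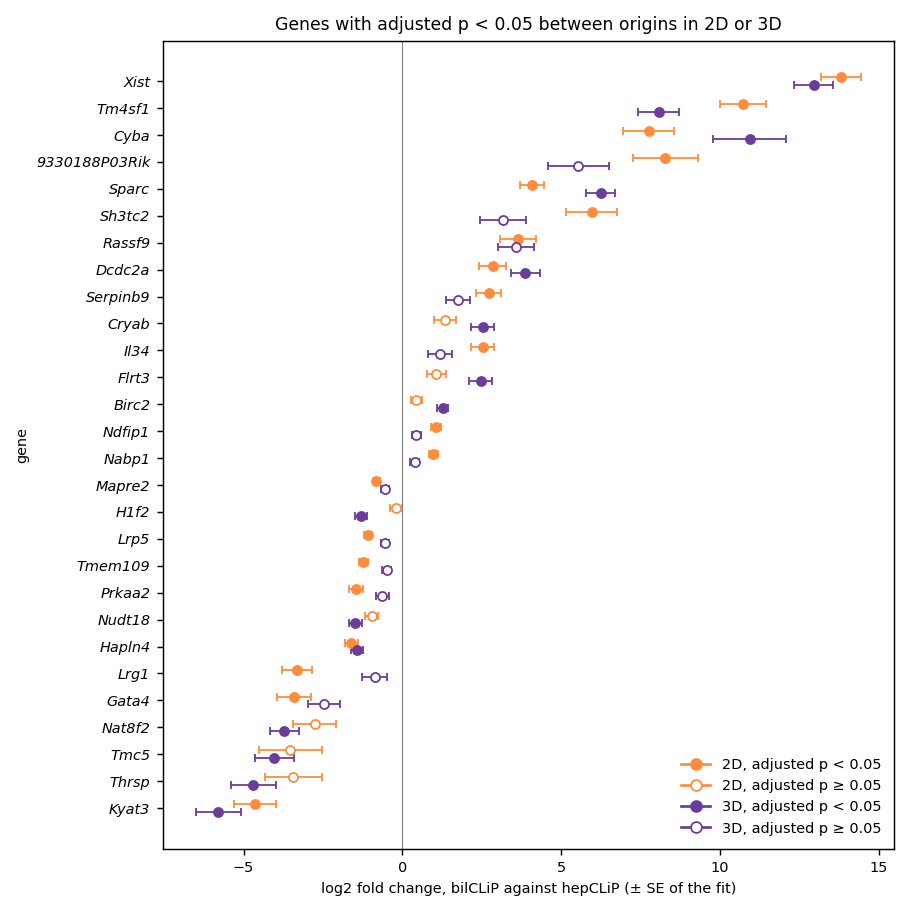
Log2 fold change of bilCLiP against hepCLiP in 2D and 3D (horizontal axis, ± SE of the fit) for the 28 genes called in at least 1 culture (vertical axis); filled points have an adjusted p under 0.05. Xist lay at 13.80 in 2D and 12.94 in 3D and Kyat3 at -4.64 and -5.79, and each gene had the same sign in both cultures.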

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

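The tests of scaling, reporter genotype and permuted lines for the cholesterol synthesis response were chosen only after that result was seen. Camera with the preset correlation called 9 gene lists for a difference between the culture effect in bilCLiP and that in hepCLiP, given as the median difference over the list's members, bilCLiP minus hepCLiP. None of the 9 passed with an estimated correlation or with fry. Besides cholesterol synthesis, the median difference was -0.695 for fatty acid synthesis (adjusted p = 2.14e-07; 0.294 with an estimated correlation), whose list level rose by 1.15 ± 0.0436 (SD, n = 3) per hepCLiP line and by 0.546 ± 0.0915 per bilCLiP line (exact permutation p = 0.1). The P450 list differed by 1.36, or 1.25 with members at their bounds (adjusted p = 1.75e-05; 0.387 with an estimated correlation; exact permutation p between lines = 0.5). Secreted plasma proteins differed by 0.842 (6.62e-05; 0.529 with an estimated correlation), with level rises of 7.04 ± 0.801 in hepCLiP and 7.65 ± 0.465 in bilCLiP lines (exact permutation p = 0.4). In RosaYFP samples only, the calls of the P450 list, secreted proteins, acute phase targets (adjusted p = 0.15), hypoxia genes (0.992) and the Wnt list (0.132) were lost. The cell cycle list differed by 0.286 (adjusted p = 0.00262; 0.762 with an estimated correlation), a call that was lost without any of 5 libraries (adjusted p 0.0925 to 0.487). Acute phase and STAT3 targets differed by 0.647 (0.00325; 0.518 with an estimated correlation) and lost their call without hepCLiP 3D replicate 3 (0.0791) or bilCLiP 2D replicate 1 (0.214). Hypoxia genes differed by -0.369 (0.00328; 0.491 with an estimated correlation), lost without hepCLiP 2D replicate 1 (0.0563), 2D replicate 3 (0.0925) or 3D replicate 3 (0.0745). The Wnt and beta-catenin list differed by 0.955 (0.00339; 0.340 with an estimated correlation), lost without hepCLiP 2D replicate 1 (0.0661) or 3D replicate 3 (0.0809). Unfolded protein response genes differed by -0.141 (0.0168; 0.573 with an estimated correlation), lost without hepCLiP 3D replicate 2 (0.276), bilCLiP 2D replicate 2 (0.145) or bilCLiP 3D replicate 1 (0.398), or without a low-count filter (0.0587).

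The cholesterol synthesis list had the smallest adjusted p of the 9 (3.23e-13; 0.357 with an estimated correlation), at a median difference of -1.03, and its level rose by 1.34 ± 0.364 (SD, n = 3) per hepCLiP line and by 0.445 ± 0.272 per bilCLiP line. With DESeq2 size factors the median difference was -1.07, so the choice between these 2 scalings is not the cause. Both rest on most genes being unchanged, so this decides nothing about a scaling error common to both. Reporter genotype stays open, because the RosaYFP samples, with 1 hepCLiP library per culture that is assumed to vary like the bilCLiP groups, gave -0.568. Chance between lines stays open as well, since the exact two-sided permutation p of 0.1 is the smallest that 3 lines against 3 can give. Origin could account for the difference but cannot be told apart from genotype or the sex of the animals here, so it remains an untested hypothesis.

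For the difference of culture effects, origin was regrouped over the libraries of each culture separately, which does not keep the 2D and 3D libraries of a line together. Of 60 such groupings out of 200 possible, the real one included, 31 gave at least its 9 called lists and the highest other gave 16, so chance cannot be excluded for these lists. With whole lines regrouped, a check chosen after seeing the data, the 10 splits are too few for a share under 0.05, and the 9 others called 5 to 14 lists and 0 genes. For called genes the real grouping gave 0, a count that all 60 groupings of libraries reach by definition, and the highest other gave 12. For each of the other comparisons the 10 splits are too few for a share under 0.05. The real and the highest other number of genes were 5139 and 0 for 3D against 2D in hepCLiP, 4485 and 0 in bilCLiP, 20 and 1 between origins in 2D, and 15 and 0 in 3D. For gene lists they were 16 and 19, 14 and 18, 11 and 12, and 9 and 15. Every other split mixes the 2 groups, which adds any difference between them to its spread and leaves part of it between the sides. Few called genes were therefore likely beforehand in the other splits, and their list counts are no measure of chance. In the culture comparisons, the 3 other splits that part all 3 same-numbered pairs called 14 to 19 lists in hepCLiP and 13 to 17 in bilCLiP, and the 6 that part 1 pair called 10 to 15 and 3 to 18, while no other split called a gene.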

How the results depend on the processing

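The limma fit with a random replicate block was chosen after seeing the data. Of named-gene values under all alternatives, 5741 kept their direction and side of the threshold, 465 lost the call, 23 gained one and 0 reversed. Of list results 2180 kept the direction of the test and the side of the threshold, 113 lost the call, 75 gained one, and in 6 the direction of the test reversed. Run also with an estimated correlation, a check added after seeing the data, no setting of the list test let a list pass. DESeq2's Wald test called 559 genes between origins in 2D, 652 in 3D and 16 for the difference between culture effects, and limma on the deposited normalized counts 38 and 26 between origins. The cause of these differences between tools was not tested. Fits of only the 2 groups compared, with fewer samples, gave 5 calls between origins in 2D and 3 in 3D. The replicate block gave 6973 calls with culture in hepCLiP and 6383 in bilCLiP, against 5139 and 4485. With the replicate block in the culture comparisons, the calls of Cyp3a11 in hepCLiP and of Krt7, cholesterol synthesis and fatty acid synthesis in bilCLiP changed, and no other call among the named genes and lists. Between origins the numbers join different lines, whose deviations correlated at only 0.0544 to 0.126, and in 2D not every library correlated best with its own number. A replicate block there, which the numbers do not support as a pairing, gave 62 calls in 2D (38.7% higher in bilCLiP) and 44 in 3D, and changed the calls of Tmc5 in 3D (log2 -3.81, adjusted p = 0.0621) and epithelial junctions in 2D (median -0.31, adjusted p = 0.0454). RosaYFP samples only, which leave 8 of the 12 samples and 1 hepCLiP library per culture that is assumed to vary like the bilCLiP groups, gave 769 calls in hepCLiP culture, 5 between origins in 2D and an r of 0.823 between the culture effects. They also reversed the median and the test for cholesterol synthesis between origins in 2D (-0.30) and cell cycle between origins in 3D (0.93). For the interferon response in the difference of culture effects only the test reversed, from lower at a median of 0.24 to higher at 1.12. They ended 5 list calls between origins in 2D, 2 in 3D and 5 for the difference of culture effects. Among the lost calls, the medians turned to 0.0077 for bile acid genes between origins in 2D and, for the difference of culture effects, to -0.014 for secreted proteins, -0.023 for the P450 list and 0.052 for hypoxia. The cause was not tested. A 2-fold threshold in the test, stricter by construction, left 1492 and 1290 calls for culture in hepCLiP and bilCLiP and 5 and 7 between origins. Without a low-count filter, which adds genes with few counts, the r between culture effects was 0.597. The called lists were then 19 with culture in hepCLiP, 14 in bilCLiP, 14 and 10 between origins in 2D and 3D, and 9 for the difference. With the filter they were 16, 14, 11, 9 and 9. The list test with an estimated correlation called 0 lists in each comparison of all samples. The rise in the level of secreted proteins in bilCLiP was 8.71 with a pseudocount of 0.1 and 6.55 with 5, against 7.65, since a larger pseudocount damps low values. With single libraries left out, the calls between origins were 6 to 31 in 2D and 3 to 251 in 3D, those for the difference of culture effects 0 to 3, and the called lists between origins in 3D 5 to 18. The cell cycle median between origins in 3D ran from -0.481 without hepCLiP 3D replicate 2 to 0.226 without hepCLiP 3D replicate 1, with 0.127 without bilCLiP 3D replicate 2, and that of the difference of culture effects from -0.046 without hepCLiP 3D replicate 2 to 0.644 without hepCLiP 3D replicate 1. In the difference of culture effects, the median of the 5 gastric and intestinal genes, -0.407 and not called, was positive and called without hepCLiP 3D replicate 2 (1.43), bilCLiP 2D replicate 2 or 3 (1.21 for each) or bilCLiP 3D replicate 1 (0.282). That of the interferon response was -0.223 and called without bilCLiP 3D replicate 2. The counts in hepCLiP and bilCLiP culture stayed at 4133 to 5227 and 3088 to 4555. DESeq2 size factors and a filter at a CPM of 1 kept every count of called genes within 1.5 times, as did the random replicate block, with 6964, 6568, 16, 12 and 0 calls. Depth limits mainly genes with few counts in 2D, where folds are bounds or ratios with wide intervals.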

Other observations

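The tests of sex chromosome genes and reporter genotype for the genes differing with origin, and those of library noise and of chromosome parts on separate genes and libraries for the chromosome shifts, were chosen only after those results were seen. Epithelial genes went both ways with culture. Gjb1, a gap junction gene of hepatocytes, rose from 8.55 ± 4.03 to 498 ± 83.9 CPM (SD, n = 3) in hepCLiP and from 2.48 ± 1.76 to 398 ± 116 in bilCLiP, and Gjb2, Cldn1 and the desmosomal gene Dsc2 rose in both. Of 24 epithelial junction and polarity genes, 9 rose and 4 fell in each origin, or 10 and 5 in hepCLiP and 9 and 4 in bilCLiP adjusted over the list alone, and the list was not called (adjusted p = 0.175 and 0.0927), though in bilCLiP it was without 2D replicate 3 (median 0.373, adjusted p = 0.0293; adjusted p = 0.336 with an estimated correlation). The Cldn1 call in bilCLiP was lost without 2D replicate 3 (adjusted p = 0.0573) or 3D replicate 2 (0.0684). Among p53 targets, Ccng1 fell from 717 ± 53.3 to 180 ± 30.1 CPM in hepCLiP and from 779 ± 102 to 238 ± 80.9 in bilCLiP, and Plk2 fell by 3.12 and 2.15 on the log2 scale. In hepCLiP 10 of 20 p53 targets fell and 2 rose, also adjusted over the list alone (median -0.74, adjusted p = 0.00619; adjusted p = 0.357 with an estimated correlation). In bilCLiP 6 fell and 1, the death receptor gene Fas, rose, or 9 and 2 adjusted over the list alone (median -0.69, adjusted p = 0.00348; adjusted p = 0.322 with an estimated correlation). Gdf15 also fell in both, though in bilCLiP not without 2D replicate 1 (log2 -1.38, adjusted p = 0.0531), 3D replicate 2 (0.0602) or 3D replicate 3 (0.0564).

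Hypoxia genes were not called as a list (adjusted p = 0.317 in hepCLiP and 0.883 in bilCLiP), with 4 rising and 1 falling of 22 in hepCLiP and 1 and 4 in bilCLiP, or 4 and 1, and 1 and 2, adjusted over the list alone. In hepCLiP the list was called without 2D replicate 2, at a median of 0.497 in place of 0.318 (adjusted p = 0.0426; adjusted p = 0.576 with an estimated correlation). The glycolytic kinase gene Hk2 fell in both origins (-1.46 ± 0.260 and -1.61 ± 0.263), and Mxi1 rose in both. Of 21 interferon response genes, 2 rose and 1 fell in hepCLiP and 2 rose in bilCLiP, or 1 rising in hepCLiP and 0 in bilCLiP adjusted over the list alone (list adjusted p = 0.479 and 0.655). None of the 13 mitochondrially encoded genes was called with culture on either adjustment, at an adjusted list p of 0.730 in hepCLiP and 0.383 in bilCLiP. Tff3, a trefoil factor of mucous epithelia, rose from 0.212 ± 0.291 to 441 ± 433 CPM in bilCLiP, where 2 of the 5 tested gastric and intestinal genes rose, or 2 rose and 1 fell adjusted over the list alone, and 1 rose in hepCLiP on both adjustments. That list was not called (adjusted p = 0.534 and 0.957), with medians of -0.47 and -0.68 but means of 1.74 and 1.46. The lists of 4 other cell types had too few tested members (4, 4, 2 and 2) for a list test. Above 5 CPM in any library were 3 of 16 stellate and fibroblast genes (Reln, Dcn and Ecm1), 3 of 12 endothelial genes (highest Flt1, 34.9 CPM), 2 of 16 macrophage and leukocyte genes (highest Csf1r, 16.9 CPM) and 2 of 10 mesothelial genes (highest Msln, 989 CPM). Ecm1 fell in both origins, whereas the Dcn log2 fold change in hepCLiP was 1.47 (adjusted p = 0.466) without 3D replicate 1, in place of 6.12.

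The library hepCLiP 2D replicate 3, whose treatment tag says 3D, had 691 CPM of Alb against 142 and 19.9 in the other hepCLiP 2D libraries, 14.1 CPM of Cps1 against 1.11 and 0.591, and 175 CPM of Cyp3a11 against 3.61 and 0.0909. Xist had 812 to 1163 CPM in every bilCLiP library and at most 0.284 in hepCLiP. The Y chromosome genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to 3353 and 2594 counts in hepCLiP replicate 1 (2D and 3D), 3783 and 3684 in replicate 3, 3 and 0 in replicate 2 and 0 in all bilCLiP libraries. HepCLiP replicate 2 thus had neither Xist (3 and 4 counts) nor Y transcripts at the levels of the others, while its X-linked genes differed from those of replicates 1 and 3 by a median of 0.03 in 2D and 0.02 in 3D (log2). Averaged over cultures by a limma fit with a random replicate block, chosen after seeing the data, 24 genes differed with origin (15 higher and 9 lower in bilCLiP), of which 18 were also called in 2D or 3D. Among them was Gt(ROSA)26Sor, the RNA of the reporter locus, with 5.99 to 14.7 CPM in bilCLiP libraries and 0.695 to 4.26 in hepCLiP libraries. Within hepCLiP, the RosaYFP line had 3.55 CPM in 2D and 4.26 in 3D, and the RosaConfetti lines 0.695 to 1.57.

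The 28 genes called between origins in 2D or 3D changed strongly, with a median absolute log2 fold change of 3.52 over 35 calls. Of the 27 genes matched to a chromosome, 1 (Xist) lay on X or Y and 26 did not, so most are not sex chromosome genes. Among the 14454 matched genes tested, 456 lay on X and 7 on Y, so few were to be found by chance as well. No Y gene was called, and hepCLiP replicate 2 almost lacks the Y transcripts of replicates 1 and 3, which widens the spread. The count of 1 does not exclude a difference in the sex chromosomes between the lines, which the Xist and Y counts show. X-linked genes had a median difference (bilCLiP minus hepCLiP) of 0.0581 in 2D and 0.147 in 3D, against -0.0788 and -0.043 for autosomal genes. Shifts of whole chromosomes came to 0.528% of the median effect. The largest between origins was -0.302 log2 (chromosome 15 in 2D), too small for a change of the median size. The genes were chosen by their call, however, so a part in smaller changes is not excluded. Tmem109 (-1.23) and Lrp5 (-1.09 in 2D), for example, lie on chromosome 19, which shifted by -0.289. Reporter genotype stays open: in RosaYFP samples the effects had a median ratio of 1.02 to those in all samples (0.700 to 1.48), but with 1 hepCLiP line. The call in all samples also favours genes whose hepCLiP lines agree, so this ratio decides nothing. The sex of the animals acting on autosomal genes, differences between single lines and the cell of origin cannot be told apart in this design, so a lasting effect of the cell of origin is a hypothesis only.

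Lines differed in the level of whole chromosomes: over 9114 genes with a mean of at least 10 CPM, 13 of 120 combinations of line and chromosome had a median shift of at least 0.1 log2 from the mean of the 3 lines of that origin in both cultures, against 0 in each of 1000 permutations of the chromosome labels, such as chromosome 14 in bilCLiP 2 (-0.45 in 2D and -0.41 in 3D), chromosome 9 in bilCLiP 1 (0.32 and 0.33) and chromosome 15 in hepCLiP 3 (-0.25 and -0.26). Library noise is argued against by correlations of 0.894 to 0.983 between a line's shifts in 2D and 3D, and GC content and gene length by the 97.6% of the shift that was kept after their trend was removed (median; lowest 69.4%). That a median of 82.2% of a chromosome's genes lay on the shifted side, and that both parts of the gene order did in 100% of cases, decides nothing about a few strong genes or copy number, since these chromosomes were chosen by their median and 1 deviating line also shifts the others from their mean (the 13 fell in 7 combinations of origin and chromosome). The first part in 2D chose 1 line in each of 11 combinations of origin and chromosome with a shift of at least 0.1. The second part in 3D lay on the same side in all 11 (median 85.7% of the shift, lowest 38.3%). The combinations not chosen, with smaller shifts, also lay on the same side throughout bilCLiP, though not throughout hepCLiP. The side alone therefore decides little. Copy number differences of whole chromosomes are a candidate explanation, which no DNA measurement tests here. In what share of the cells they would lie is not known.

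Between origins (bilCLiP against hepCLiP), the median log2 fold changes of chromosomes 14, 15 and 19 were -0.27, -0.30 and -0.29 in 2D. In 3D they were -0.25, -0.27 and -0.27. Single lines also shifted from the mean of their origin. In 2D, bilCLiP 2 shifted by -0.452 on 14, hepCLiP 3 by -0.254 on 15 and hepCLiP 2 by 0.15 on 19. The hepCLiP 3 shift runs against the lower bilCLiP median on 15. The hepCLiP 2 shift is smaller in size than the median on 19. These lines therefore do not account for all 3 medians. With 3 lines per origin, and genotype and sex chromosome transcripts differing along with it, the medians still cannot be assigned to origin.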
